A study of Mus musculus with 4 samples.

How the data were processed

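RNA from mouse primary intestinal epithelial cells was measured on 4 Affymetrix expression arrays, 1 for each of 4 groups: untreated cells, and cells stimulated for 6 h with interleukin-17A (IL-17A, 50 ng/ml), fibroblast growth factor 2 (FGF2, 5 ng/ml) or both. Per the labels' protocols, isolated crypts were plated on fibronectin, total RNA was extracted with a column kit, and biotin-labelled cRNA was made with a kit that primes from the 3′ end of the transcript. The labels describe the cells as epithelial, and no step that removes other cells of the intestinal wall was given in the sources used here. The culture time of the untreated cells was not given either.

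The deposited values are log2 signals, 1 per probe set and array. Per the submitters' processing notes the authors summarised the probes with MAS5, whose version was not given in the sources used here. MAS5 subtracts the signal of mismatch probes, so values near background are noisy, and it scales each array as a whole. In the deposited values, the antilog signals had a 2% trimmed mean of 500 on every array, so the arrays had been scaled to a common target before the log2 was taken. Exact 0s numbered 153, 197, 178 and 224 on the untreated, IL-17A, FGF2 and combined arrays, as signals of 1 or less would give. Detection calls were not analysed here.

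Of 45101 probe sets, 64 were control probe sets and were left out of the comparisons. Gene symbols came from the platform annotation, which gave 1 symbol for 34945 probe sets, several for 932 and none for 9160. Of these symbols, 34741 were matched by Entrez identifier to the GRCm38.p6 gene table, and 0 changed. Probe sets with several symbols or none entered no gene result. A gene was represented by the probe set with the highest mean log2 signal among those with 1 symbol, which gave 18193 genes, 9010 of them with several probe sets. Signals under the floor, the median of all signals of the 4 arrays (signal 89.8, log2 6.49), were raised to it, and 12258 genes were over it on at least 1 array and are called measured. A fold from or to a floored signal is a lower bound.

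With 1 array per group there are no replicates, the number of arrays limits the precision, and no test, p-value or standard error across samples was computed. An additive fit of both factors would leave 1 residual degree of freedom per gene, the interaction, which served as a yardstick and not as a test because it is itself a subject of the series. Each comparison gives log2 ratios per gene and the number of genes at least 2-fold higher or lower. A yardstick of error came from the layout: the effect of each factor can be read from 2 pairs of arrays that share none, and the interaction (log2 combined − IL-17A − FGF2 + untreated) is the difference between these readings. Taken as error, it gave an SD of a log2 ratio of 0.29 for measured genes with a mean log2 signal under 8, 0.20 for 8 to 10, 0.13 for 10 to 12 and 0.09 over 12. The 99th percentiles of the absolute values were 0.83, 0.62, 0.39 and 0.30. True interaction is part of this yardstick and raises it, while raising dim signals to the floor lowers it. For genes near the floor it is therefore not an upper estimate of the error. Log2 ratios of different probe sets of a gene, all over the floor on all arrays, had a within-gene SD of 0.21 to 0.25 over 4676 genes.

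Before the data were examined, 38 gene lists were fixed, 25 of processes and 13 of cell type markers, with 739 entries of which 71 had no matching gene. The median log2 ratio of a list's measured members was placed among 10000 random lists of the same size matched on mean expression in 20 bins. These percentiles describe these arrays and are not tests. The family held 228 values, 38 lists in 5 comparisons and the interaction. If list members varied independently, chance alone would put 0.95 of 38 lists in each tail outside the 2.5th or 97.5th percentile. Lists whose members vary together would fall there more often. The rule for named genes, fixed at the same time, took per comparison with untreated cells the 10 highest and 10 lowest ratios among genes at least 2-fold different whose other probe sets over the floor in either array went the same way. It took 5 and 5 for the combination against each factor alone, the 15 genes highest and 5 lowest on the combined array by the fold to the nearest other array, and any member of the fixed lists. Clone and model symbols were counted but not named.

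Alternatives fixed beforehand were 2 other scalings, floors at the 25th and 75th percentiles, addition of the floor to the signal, the mean of all probe sets of a gene, the omission of probe sets that can detect related transcripts, and fold thresholds of 1.5 and 3. Averages of each factor's effect over both pairs of arrays were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were tested on simulated arrays of 18193 genes in which 200 genes were given known differences in the IL-17A against untreated comparison. The 2-fold threshold called 65 of 67 genes planted at 2.5-fold, 66 of 66 at 4-fold and 0 of 67 at 1.5-fold, and it called 1 unchanged gene. All planted genes had a mean log2 signal more than 2 units above the floor, so recovery among dimmer genes was not tested. The simulated noise was normal with its SD taken from the interaction, so the 1 unchanged gene is no error rate for the real arrays. A planted list of 20 genes shifted by 0.3 log2 units came out at a median of 0.33 and the 100th percentile. Of 100 lists drawn at random, 5 lay outside the 2.5th to 97.5th percentiles. Random drawing sets this share by itself, so it checks the calculation and does not describe lists whose members vary together.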

Results

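The series set out to see how IL-17A, a cytokine of T cells and innate lymphocytes, and FGF2, a growth factor acting through receptor tyrosine kinases, work together on intestinal epithelium, as its title states. The data are the signals of 18193 genes on 4 arrays, from untreated cells and cells given IL-17A, FGF2 or both. There are no replicates, so every difference below is a difference between arrays. Signals correlated across measured genes with r from 0.968 (untreated and combined) to 0.984 (untreated and IL-17A), and genes are not independent replicates. The 3′ to 5′ signal ratio of the Actb control probe sets lay between 1.18 and 1.25, and that of Gapdh between 0.82 and 0.87. Markers of other cell types of the intestinal wall were measured in every group: over the 4 arrays the fibroblast collagen gene Col1a2 had signals of 8360 to 13833, the endothelial gene Emcn 2063 to 3504 and the glial gene Sox10 531 to 668. Signals of different probe sets do not give the relative amounts of these cells.

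After IL-17A alone, neutrophil-attracting chemokine genes led the named genes above untreated cells. Cxcl5 was 12.3-fold higher (signals 316 and 3878), Cxcl1 9.48-fold, the cytokine gene Il6 6.41-fold and Lcn2, whose product binds bacterial siderophores, 5.19-fold. Zc3h12a, which encodes a ribonuclease that degrades cytokine mRNAs, was 4.96-fold higher, and Pigr, the carrier of IgA across epithelium, 4.89-fold. Named genes below untreated cells included Slc10a2, the ileal bile acid transporter (2.78-fold lower), the apolipoprotein gene Apob (2.77-fold), the uroguanylin gene Guca2b (2.75-fold) and Agr2, a disulfide isomerase of goblet cells (2.97-fold). In all, 46 genes were at least 2-fold higher and 28 at least 2-fold lower. These counts depended on the floor and were 20 and 8 with it at the 75th percentile of signals, and 216 and 250 at the 25th.

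The other named genes above untreated cells were Sprr2h (8.45-fold), Sprr2f (4.68-fold) and Sprr2d (at least 4.64-fold), small proline-rich proteins whose probe sets can detect related family members, and the prolactin-family gene Prl2a1 (6.74-fold). Below untreated cells were Tcl1b3 (4.31-fold), Cyp3a11 (3.65-fold), Pkp1 (at least 3.05-fold), Dmp1 (at least 2.72-fold), Slc30a10 (2.71-fold) and Accs (at least 2.69-fold). The probe set of Tcl1b3 can also detect related transcripts.

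By list, neutrophil and monocyte chemokines had a median log2 ratio of 0.95 for IL-17A against untreated, with 9 of 11 measured members above 0 and 5 at least 2-fold higher, among them Ccl7 at 2.63-fold and Ccl20 at at least 2.19-fold. Inflammatory cytokines and colony-stimulating factors had a median of 0.47, with 5 of 14 at least 2-fold higher, including Il11 at 2.15-fold, Csf3 at 2.18-fold and Tnf at at least 2.33-fold. Genes of NF-kB feedback had a median of 0.23, with Tnfaip3 1.75-fold and Ier3 1.62-fold higher, and 12 of 17 above 0. Nfkbiz was 2.87-fold higher in its brightest probe set, while another of its probe sets went the other way. Antimicrobial and acute phase genes had a median of 0.31, with Saa3 2.72-fold and Steap4 3.55-fold higher but Reg3b 2.28-fold lower. Among mucins, Muc1 was 3.82-fold higher and Muc2 1.37-fold lower. These 5 lists, and hypoxia and glycolysis genes at 0.14 and ribosomal proteins at 0.15, lay at the 99.9th percentile or above of matched random lists. Ligand and receptor genes of the EGF family were at 0.15 (99.7th percentile). In the other pair for IL-17A, both factors against FGF2, they were at −0.13 (1.2th percentile). Some of the medians against untreated depended on processing. Ribosomal proteins were at 0.01 (72.5th) under quantile normalization, and mucins at 0.00 (40.1th) with the floor at the 75th percentile. The EGF family was at 0.01 (66.3th) with the floor at the 25th and 0.08 (95.6th) at the 75th. Genes of IL-17 receptor signalling lay at 0.05 (89.8th percentile).

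Enterocyte markers were the list furthest below untreated cells after IL-17A, with a median of −0.80 and 17 of 19 measured members below 0. Fabp2 was 2.27-fold, Slc26a3 2.12-fold, Alpi 2.12-fold and Apoa1 1.90-fold lower. General epithelial markers had a median of −0.05 (0.1th percentile), with Krt8 1.08-fold higher and Vil1 1.18-fold lower. Interferon-stimulated genes had a median of −0.14, and of −0.07 (3.7th percentile) with the mean of all probe sets. The fibroblast list was at 0.01 and the goblet list at −0.04, inside the range of random lists, and the endothelial list was at −0.14 (2.0th percentile), while in the other pair for IL-17A, both factors against FGF2, it was at 0.13 (98.6th percentile). The first of these values was inside the range with the floor at the 75th percentile (−0.10, 6.0th) and under quantile normalization (−0.13, 2.8th).

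FGF2 alone was compared with untreated cells to see its own response. Of the named genes above untreated cells, Cemip, needed for hyaluronan degradation, was 10.4-fold higher, Il11 9.65-fold (signals 1404 and 13544), Mmp3 5.31-fold and Mmp9 4.55-fold. Cxcl2 was 4.87-fold and Arg2, an arginase gene, 4.52-fold higher. Of those below, Agt was at least 6.62-fold lower, Aldh1a1, a retinoic acid-forming enzyme, 5.23-fold, Igf1 5.09-fold, and the matrix protein genes Dpt and Aspn 4.50- and 4.12-fold. At least 2-fold differences numbered 58 genes higher and 118 lower. With the floor at the 75th percentile they were 29 and 29 and at the 25th 214 and 439.

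Other named genes above untreated cells with FGF2 were Ramp3 (7.38-fold), Sptssb (5.73-fold), Rgs1 (4.44-fold) and the T cell receptor segment Trbv1 (4.96-fold), whose probe set can detect related transcripts. Those below were Rims1 (at least 4.85-fold), Pdlim3 (4.40-fold), Itih5 (4.25-fold), Ifitm1 (4.16-fold) and Agr2 (4.12-fold).

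Feedback genes of FGF and ERK signalling had a median log2 ratio of 0.20 with FGF2, and 18 of 20 measured members were above 0, for example Spry4 at 1.57-fold, Etv4 at 1.66-fold and Dusp4 at 1.46-fold. Cell cycle lists were also above random lists: 23 of 26 genes of G1/S and replication were above 0 (median 0.31; Mcm7 1.30-fold, Cdc6 1.48-fold) and 24 of 26 of G2/M (median 0.32; Ube2c 1.62-fold, Mki67 1.31-fold). Matrix, protease and wound repair genes had a median of 0.21, with 6 of 37 at least 2-fold higher, including Mmp13 at 4.03-fold, Ptges at 2.99-fold and Plau at 2.75-fold. Ligand and receptor genes of the EGF family were at 0.18, with Epgn 3.83-fold higher, the unfolded protein response at 0.16 and heat shock genes at 0.17. With the mean of all probe sets these 3 lists were inside the range of random lists (0.13 at the 93.7th percentile, 0.11 at the 96.8th and 0.13 at the 96.1th), as were heat shock genes without probe sets open to related transcripts (97.4th). Immediate early genes were at 0.10 (94.8th percentile), with Egr3 2.23-fold higher.

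Below random lists with FGF2 were enterocyte markers (median −0.53, 17 of 19 below 0), antimicrobial and acute phase genes (−0.40; Saa3 3.86-fold lower, S100a8 3.22-fold higher), goblet markers (−0.42; Spdef at least 1.90-fold and Fcgbp 1.48-fold lower), Paneth markers (−0.43, 5 measured), interferon-stimulated genes (−0.20) and apoptosis genes (−0.14). With the mean of all probe sets of a gene the apoptosis median was 0.0090 (55.9th percentile), and with the floor at the 75th percentile the antimicrobial median was 0.00 (46.9th). Fibroblast markers were at −0.36 with 19 of 23 below 0: Pdgfra was 2.13-fold, Col1a1 2.09-fold and Myh11 1.98-fold lower. Endothelial markers were at 0.34 with 12 of 13 above 0, for example Flt1 at 1.77-fold. FGF ligands, receptors and signalling genes were at −0.12 (7.5th percentile). The fibroblast and endothelial values stand beside the matrix, cytokine and cell cycle genes above, whose cell of origin these arrays do not show. The poly-A spike controls had their lowest mean log2 signal, 9.16, on the FGF2 array, against 9.76 to 10.29 on the others.

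With IL-17A and FGF2 together, the named genes above untreated cells included some, but not all, of those leading with either factor. Cxcl2 was 28.7-fold, Cxcl1 24.7-fold and Il6 23.9-fold higher, and Cemip 16.3-fold, Cxcl5 13.8-fold and Il11 11.3-fold. Sprr2h was 9.23-fold, S100a8, a subunit of calprotectin, 8.93-fold, Mmp9 8.77-fold and Arg2 8.28-fold higher. Named genes below were Aldh1a1 (7.33-fold), Slc10a2 (at least 6.67-fold), Agt (at least 6.62-fold), Pdlim3 (at least 6.57-fold), Agr2 (at least 6.11-fold), Igf1 (5.45-fold), Adamdec1 (5.26-fold), Itih5 (5.02-fold), Rims1 (at least 4.85-fold) and Itga8 (4.79-fold). The counts were 111 genes at least 2-fold higher and 212 lower. The 75th percentile floor gave 56 and 58, and the 25th 295 and 618.

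The lists at the extremes under the combination were chemokines (median log2 ratio 1.51, 6 of 11 at least 2-fold higher), inflammatory cytokines (0.51), NF-kB feedback (0.31), FGF and ERK feedback (0.35), matrix and proteases (0.26, 9 of 37 at least 2-fold higher), the cell cycle lists (0.26 for G1/S and 0.25 for G2/M), ribosomal proteins (0.25), hypoxia and glycolysis genes (0.24), heat shock genes (0.23) and the unfolded protein response (0.19). Under quantile normalization ribosomal proteins (0.04), hypoxia and glycolysis (0.07) and heat shock genes (0.02) were inside the range of random lists. The unfolded protein response (0.10, 90.9th percentile) and heat shock genes (0.12, 85.2th) were so with the mean of all probe sets, and both without probe sets open to related transcripts (0.15, 94.5th; 0.11, 61.4th). Matrix and proteases were so with the floor at the 75th percentile (0.13, 95.2th). Enterocyte markers had a median of −1.18, with all 19 measured members below 0 and 13 at least 2-fold lower, such as Slc26a3 at 3.83-fold and Fabp2 at 3.36-fold. Fibroblast markers (−0.39), interferon-stimulated genes (−0.38), goblet markers (−0.33) and enteroendocrine markers (−0.21) were also below random lists, the last with a median of 0.0229 when the floor was at the 75th percentile and inside the range under 3 other alternatives (−0.18, −0.15 and −0.10). Endothelial markers were at 0.45 and glial and neuronal markers at 0.23. Antimicrobial and acute phase genes were at 0.09, inside the range, with S100a8 and Lcn2 above and Reg3b 3.44-fold below.

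Set against IL-17A alone, the combined array gives the difference that went with FGF2 in the presence of IL-17A. Mmp9 was 7.69-fold, Cemip 7.33-fold, Cxcl2 6.87-fold, Arg2 5.66-fold and Mmp13 5.39-fold higher. Aldh1a1 was 5.14-fold, Pdlim3 at least 5.07-fold, Itih5 4.86-fold, Agt at least 4.71-fold and Adamdec1 4.65-fold lower. In this pair 67 genes were at least 2-fold higher and 105 lower. The counts were 35 and 26 with the higher floor and 274 and 442 with the lower. FGF and ERK feedback (0.20), G1/S (0.31), G2/M (0.28), EGF family (0.24), matrix (0.11), glial and neuronal (0.23) and endothelial genes (0.56) were above random lists, and fibroblast (−0.46), antimicrobial (−0.43), enterocyte (−0.44), goblet (−0.42) and interferon-stimulated (−0.22) genes below. With the mean of all probe sets the EGF family (0.06, 83.0th percentile) and the glial and neuronal list (0.12, 96.3th) were inside the range.

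Set against FGF2 alone, the combined array gives the difference that went with IL-17A in the presence of FGF2. Cxcl5 was 11.7-fold, Sprr2h 9.41-fold, Cxcl1 8.61-fold, Il6 8.37-fold and Zc3h12a 8.32-fold higher. Rrp9 was 4.31-fold, Fgf15, the ileal hormone that restrains bile acid synthesis, 2.65-fold, Slc25a48 at least 2.47-fold, Slc10a2 at least 2.45-fold and Tm4sf4 2.44-fold lower. Of the named genes, Rrp9 also stood furthest below all other arrays on the combined array, so a deviation of that array could give its value. Against FGF2 alone 45 genes were at least 2-fold higher and 33 lower. They numbered 25 and 9 with the higher floor and 282 and 279 with the lower. Chemokines (1.29), antimicrobial genes (0.59), inflammatory cytokines (0.33), mucins (0.25), NF-kB feedback (0.25), ribosomal proteins (0.14), endothelial markers (0.13) and neutrophil markers (0.46, 3 measured) were above random lists. Enterocyte markers (−0.57), the EGF family (−0.13), interferon-stimulated genes (−0.10), cholesterol biosynthesis genes (−0.10) and fibroblast markers (−0.05) were below. Among these, 7 came inside the range under an alternative: ribosomal proteins under quantile normalization (0.03, 83.1th percentile), mucins with the floor at the 75th percentile (0.12, 94.9th) and neutrophil markers with it at the 25th (0.31, 95.7th). With the mean of all probe sets the EGF family (−0.12, 4.5th), interferon-stimulated genes (−0.06, 11.9th), cholesterol biosynthesis genes (−0.10, 3.3th) and fibroblast markers (−0.03, 21.9th) did so too. Other alternatives that ended these calls were quantile normalization for the EGF family (2.8th), the added floor for interferon-stimulated genes (3.4th), and the omission of probe sets open to related transcripts for ribosomal proteins (97.2th) and fibroblast markers (−0.0050, 17.2th).

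The response to each factor could thus be read from pairs of arrays with none in common. For IL-17A, 25 genes were at least 2-fold higher in both pairs, against 0.169 from n1 × n2 / N with N the 12258 measured genes, and 12 were lower in both, against 0.0754. This product takes every measured gene as equally likely to pass 2-fold. Error was larger in dim genes, so the product is too low as a chance count. Across all 18193 genes the correlation of the log2 ratios was r = 0.356 and rho = 0.18. For FGF2, 44 genes were higher in both pairs (0.317 from n1 × n2 / N) and 52 lower in both (1.01), with r = 0.592 and rho = 0.437. These values depended on the floor: with it at the 75th percentile, at the 25th or added to the signal, genes higher and lower in both pairs were 16 and 6, 36 and 33, and 21 and 1 for IL-17A (r = 0.519, 0.147 and 0.254). For FGF2 they were 24 and 15, 57 and 100, and 34 and 27 (r = 0.708, 0.324 and 0.461). With the mean of all probe sets, 7 and 34 genes were lower in both pairs for IL-17A and FGF2. No gene, 0 for either factor, was at least 2-fold different in opposite directions. With so few genes called, unrelated pairs would give few or none as well, so this adds little. Cxcl5 under IL-17A (12.3- and 11.7-fold higher) and Aldh1a1 under FGF2 (5.23- and 5.14-fold lower) are examples of genes alike in both pairs.

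**Figure D1:**
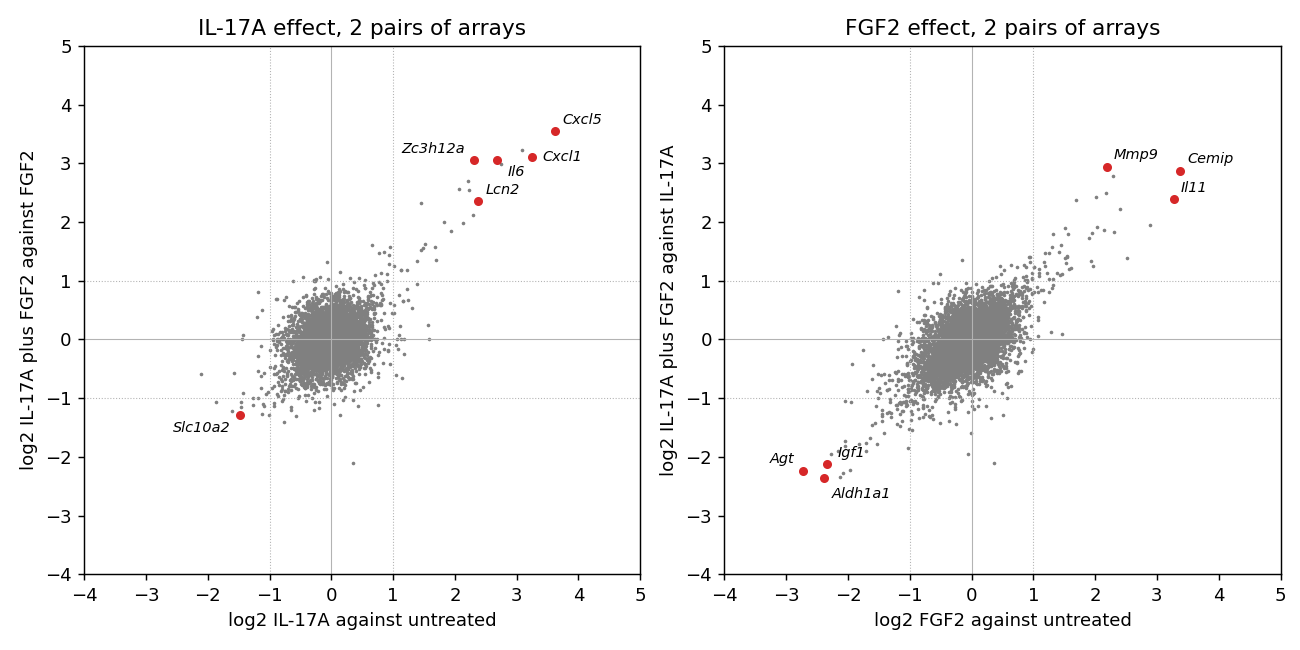
Log2 ratios of 12258 measured genes for IL-17A (left; IL-17A over untreated on the horizontal axis, combined over FGF2 on the vertical) and FGF2 (right; FGF2 over untreated, combined over IL-17A), with 1 point per gene, dotted lines at 2-fold and named genes in red. Cxcl5 lies at 12.3- and 11.7-fold higher in the left panel, and Aldh1a1 at 5.23- and 5.14-fold lower in the right.

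**Figure D2:**
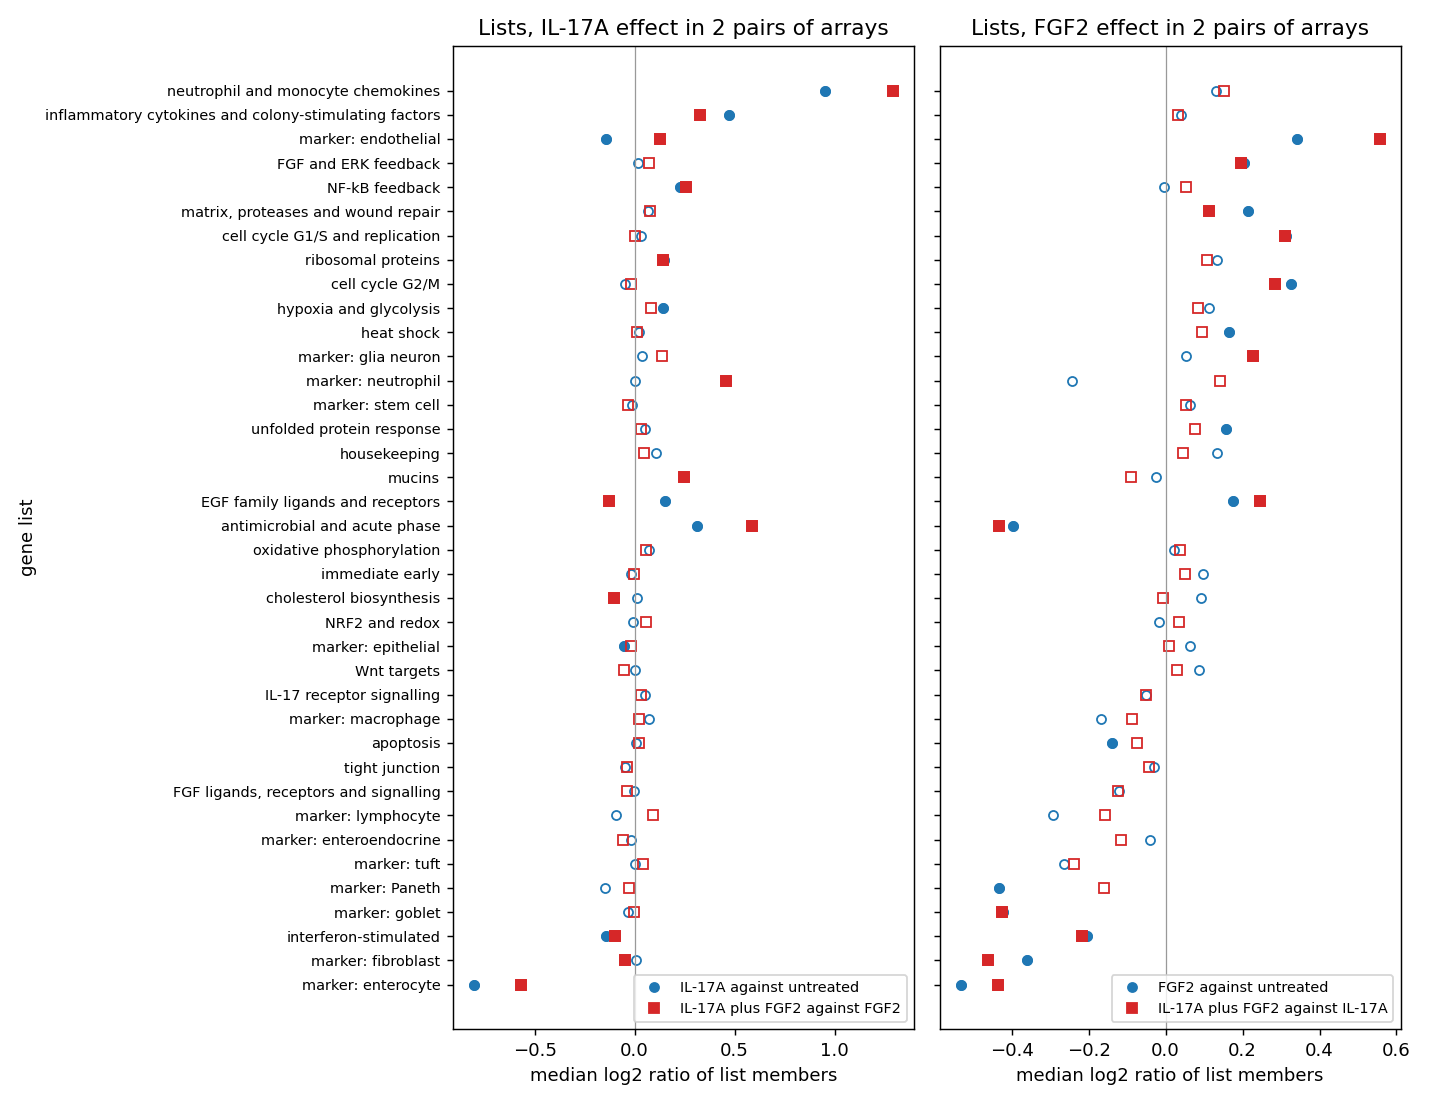
Median log2 ratio of the measured members of the 38 gene lists for IL-17A (left) and FGF2 (right), each read from 2 pairs of arrays (circles and squares), with filled symbols for medians outside the 2.5th to 97.5th percentiles of matched random lists. Chemokines lie at 0.95 and 1.29 for IL-17A, and enterocyte markers below 0 in all 4 series of points.

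Cooperation between the factors, the subject of the title, was examined through genes that stood highest on the combined array. In 40 genes the combined signal was at least 1.5-fold above each of the other arrays, and Cxcl2 (5.89-fold above the next array), Il6 (3.73-fold), S100a8 (2.77-fold), Cxcl1 (2.60-fold) and Lif (2.42-fold) led them. Then came Mmp9 (1.93-fold), Hcar2 (1.90-fold), Arg2 and the cystine transporter gene Slc7a11 (1.83-fold each), Il13ra2 (1.78-fold), Nlrp3 (1.73-fold), Cxcl3 (1.71-fold), and Abcb1b, Sprr2f and Dio2 (1.70-fold each). Of the 40, 23 were at least 2-fold above untreated cells and 11 were at least 1.5-fold higher with each factor alone. The same count was 86 for untreated, 35 for IL-17A and 13 for FGF2, so the number alone does not set the combined array apart. In 79 genes the combined array was lowest by 1.5-fold, against 36, 17 and 45 for untreated, IL-17A and FGF2. With the floor at the 75th percentile, 16 genes were highest and 10 lowest on the combined array, and at the 25th 234 and 324. Rrp9 (3.36-fold below the next array), Slc25a48 (at least 2.47-fold), Fgf15 (2.43-fold), Slc10a2 (at least 2.40-fold) and Zap70 (2.29-fold) were furthest.

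**Figure D3:**
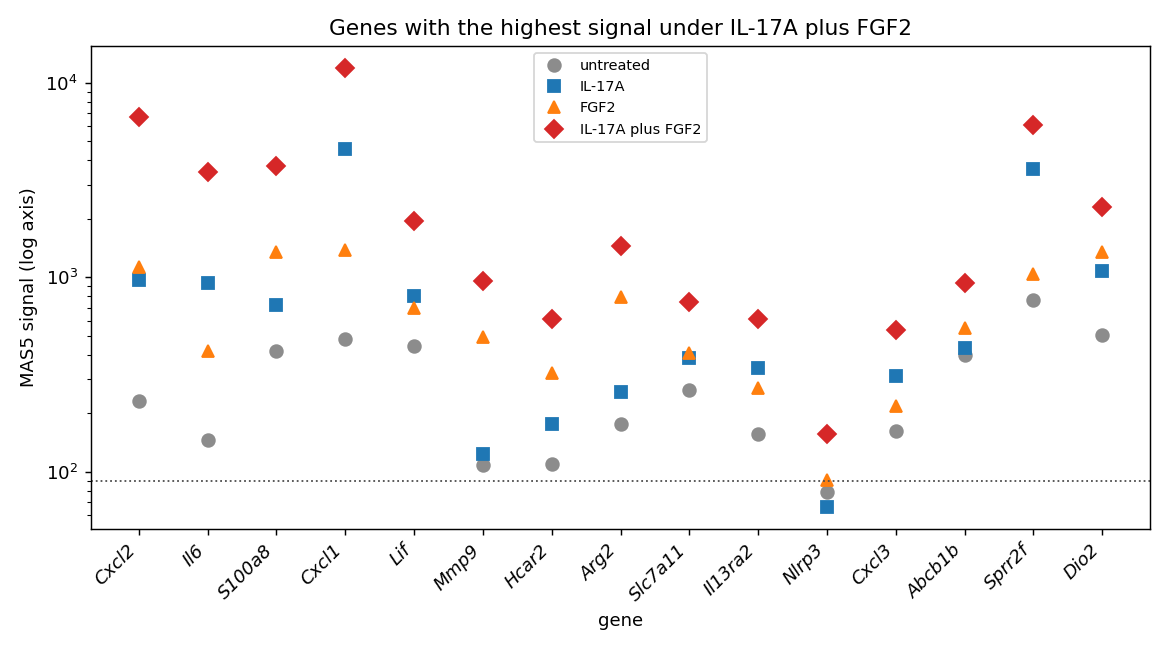
MAS5 signals on a log axis of the 15 named genes with the highest combined signal relative to the next array, with 1 point per array (grey untreated, blue IL-17A, orange FGF2, red both) and a dotted line at the floor of 89.8. Cxcl2 goes from 232 in untreated cells to 969 and 1130 with either factor and 6656 with both.

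The joint fold was set against the product of the separate folds. On the log scale their difference is the interaction, which is also the yardstick of error, so an excess over the product cannot be told from error here. Cxcl2 was 28.7-fold above untreated against a product of 20.3, Il6 23.9-fold against 18.3 and Cxcl1 24.7-fold against 27.2, and S100a8 was 8.93-fold against 5.51 and Mmp9 8.77-fold against 5.19. Across the 40 genes highest on the combined array the median log2 interaction was 0.62, and across the 79 lowest on it −0.51, values that choosing genes by the combined signal pushes upward and downward. The joint increase in signal of Cxcl2 was 3.93 times the sum of the separate increases. Folds above 1 that only multiply also exceed that sum, so this value is no measure of interaction. Of 20 genes at least 1.5-fold higher with each factor by averaged effects, 19 had a joint increase above the sum. The median log2 interaction of these 20 was 0.10. Il11 was 11.3-fold higher against a product of 20.7, but its signal with FGF2 alone was already among the brightest on the arrays. A further increase may not be fully measured there, so this shortfall does not show an interaction. Over all genes the log2 interaction was at or above 1 in 54 and at or below −1 in 49, and these genes were dim, with a median log2 signal of 7.32 against 9.23 for measured genes. With the floor at the 75th percentile these counts were 5 and 1, and at the 25th 574 and 500. Rrp9, at −2.46, was furthest below 0 of the named genes. Of the lists, 0 had an interaction above the 97.5th percentile and 5 below the 2.5th: EGF family (−0.22), cholesterol biosynthesis (−0.12), immediate early (−0.07), stem cell (−0.18) and fibroblast (−0.07) genes. Each of these 5 was inside the range under at least 1 other way of processing, and the fibroblast median was 0.0001 with the mean of all probe sets.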

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

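The tests of uniform shifts in the fibroblast and enterocyte lists and of the epithelial share were chosen after the result was seen. The scaling and pancreatic tests were set before their values were seen.

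In 11 genes the difference with IL-17A was at least 1.5-fold in opposite directions without and with FGF2, and in 7 the difference with FGF2 was so without and with IL-17A. These were 13 genes, 5 of them on both lists, and the differences between the pairs were not tested. All were dim, with mean log2 signals up to 8.61. Unc93b1, chosen after its values were seen, had signals of 349, 205, 205 and 326 in untreated, IL-17A, FGF2 and combined cells.

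Among 10092 probe sets without a single gene symbol, which enter no gene result, 4 were at least 2-fold higher and 11 lower with IL-17A than in untreated cells, 15 and 15 with FGF2, and 16 and 28 with both. The highest with FGF2 was 4.23-fold higher with FGF2 (signals 218 and 923) and 3.88-fold with both.

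Fibroblast markers were lower with FGF2 in both pairs of arrays, and the members' ratios in the 2 pairs correlated with r = 0.893 across 23 genes. Array scaling was tested by quantile normalization, which left the median at −0.35 (−0.36 as deposited) and so speaks against it. Fewer fibroblasts stay open: 14 of 16 members under the brightest range were below 0, the direction a loss would give. Their averaged FGF2 effects were unequal (−1.18 to 0.18, SD 0.417 against 0.117 expected from error), but members shared with other cells, such as smooth muscle genes, or regulated ones would differ too. A response of these cells to FGF2 also stays open, since no table separates the cells.

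Enterocyte markers were lower with IL-17A in both pairs of arrays (r = 0.634 across 19 genes). A smaller share of epithelial cells would lower epithelial markers by as much. However, 6 of them under the brightest range had a median of −0.13, against −0.57 for the 18 enterocyte markers in that range. Over the whole lists the medians were −0.04 (17 epithelial markers, 7 above 0 and 10 below) and −0.66 (19 enterocyte markers). The 6 epithelial markers under the brightest range were all below 0 (−0.30 to −0.02). A smaller share could thus account for a part of the difference but not for its size. Quantile normalization left the enterocyte median at −0.67, against −0.66, which speaks against array scaling. Loss of enterocytes stays open, since 18 of 18 markers under the brightest range were below 0, with effects down to −1.31 that were unequal (SD 0.392 against 0.156 from error) but could be so with shared or regulated markers. A response of the cells to IL-17A also stays open, since no table separates it from such a loss.

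The pancreatic enzyme genes Prss2 and Ctrb1 and the gene Reg2, noticed in the data, had their highest signals with IL-17A alone (226, 419 and 271, against 102, 170 and 91 untreated). With FGF2 present, adding IL-17A went with a higher signal in Ctrb1 (148 and 216) but a lower one in Prss2 (146 and 92), and Reg2 was under the floor in both. If pancreatic RNA in the IL-17A sample were the source, other acinar genes would peak there too. Of the 6 measured, 1 did (Cela1, with 465 against 455 untreated), which met the criterion set beforehand against that source. However, Clps, Cela3b and Cpb1 lay near the floor. Cela1, Sycn and Pnliprp2 had untreated signals of 455, 782 and 2941, which could hide a small addition. The count therefore does not decide whether pancreatic RNA was present. The other 10 acinar genes were under the floor on all arrays, 5 of them with their highest value on the IL-17A array, where values have no order, so a trace of such RNA is not measured here. A response of the 3 genes to IL-17A stays open, since its test used the 6 other genes, which were not higher with IL-17A (median −0.070, and −0.023 with FGF2 present) and so have no bearing on it.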

How the results depend on the processing

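The averages over both pairs of arrays were chosen after seeing the data, and the other 10 settings before. No paired analysis was possible because each group has 1 array. Counts were held to be alike within 1.5 times, correlations within 0.1, gene ratios within the SD drawn from the interaction and list medians within the SD of the random lists. Counts are given as higher and lower for IL-17A, FGF2 and both against untreated, then both against IL-17A and against FGF2. They were 46 and 28, 58 and 118, 111 and 212, 67 and 105, 45 and 33 as reported. With the floor at the 25th percentile they were 216 and 250, 214 and 439, 295 and 618, 274 and 442, 282 and 279. At the 75th percentile they were 20 and 8, 29 and 29, 56 and 58, 35 and 26, 25 and 9. With the floor added to the signal they were 30 and 17, 39 and 59, 76 and 132, 44 and 56, 35 and 13. A threshold of 1.5-fold gave 176 and 239, 287 and 591, 410 and 799, 343 and 501, 224 and 252 by its construction, and 3-fold gave 16 and 3, 18 and 22, 43 and 44, 18 and 20, 17 and 1. The mean of all probe sets gave 78 genes lower with FGF2 against untreated in place of 118. The averages over both pairs gave 18 lower for IL-17A in place of 28. Genes highest and lowest on the combined array (40 and 79) were 234 and 324, 16 and 10, and 23 and 49 with the lower, higher and added floors, and 6 and 9 at 2-fold. Genes with an interaction at or above 1 and at or below −1 (54 and 49) were 574 and 500, 5 and 1, and 32 and 39 with these floors, and 30 and 26 with the mean of all probe sets. Genes higher and lower in both pairs for IL-17A (25 and 12; r 0.356) were 36 and 33 (r 0.147), 16 and 6 (r 0.519), and 21 and 1 (r 0.254) with these floors, and 7 were lower with the mean of all probe sets. For FGF2 (44 and 52; r 0.592) they were 57 and 100 (r 0.324), 24 and 15 (r 0.708), and 34 and 27 (r 0.461), and 34 were lower with the mean. Apart from the thresholds, the cause was not tested. Under both other scalings and without probe sets open to related transcripts, the counts and correlations listed here stayed within these bounds, and no setting moved the median of measured genes by more than 0.0358 log2 units. Quantile normalization moved the share of higher genes for both against FGF2 from 57.7% to 68.1%. The floor moved such shares further. At the 75th percentile it took FGF2 against untreated from 32.95% to 50.0% and both against IL-17A from 38.95% to 57.38%. At the 25th it took IL-17A against untreated from 62.16% to 46.35%. Of 228 list medians, 44 lay over the 97.5th and 31 under the 2.5th percentile, with ranges of 42 to 49 and 25 to 36 over the settings. Of these 75, 45 stayed outside under every alternative and 30 came inside under at least 1: 17 with the mean of all probe sets, 9 under quantile normalization, 7 and 5 with the higher and lower floors, 6 without probe sets open to related transcripts and 2 with the floor added. Lists with too few measured genes in a setting gave no value there. Signs turned for 3 called list medians: apoptosis with FGF2 (−0.14 to 0.0090) and the fibroblast interaction (−0.07 to 0.0001) with the mean of all probe sets, and enteroendocrine markers with both factors (−0.21 to 0.0229) with the higher floor, and the cause was not tested. Of the other values of lists, 1343 stayed within the spread and 220 left it, and of those of named genes 520 and 174, none with a turned sign.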

Other observations

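The analysis of averaged effects and of enterocyte subsets was chosen after the result was seen.

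Averaged over both pairs of arrays, 20 genes were at least 1.5-fold higher with each of IL-17A and FGF2 and 42 were lower with each. All 4 arrays enter both averages, so a deviation on the untreated or combined array alone would move both the same way, and no chance count is given. The first group held Cxcl1, Cxcl2, Cxcl3, Il6, Il11, Lif, S100a8, Arg1, Arg2 and Slc7a11, and the second Slc10a2, Slc51a, Slc51b, Fgf15, Fabp2, Rbp2 and Reg3b. The median interaction of the first group was 0.10, above 0 in 13. Another 16 genes were higher with IL-17A and lower with FGF2, among them Saa3, Steap4, Pigr, Ptx3, Cp, Mmp7 and Ifitm1. Only Tcl1b3, 1 gene, was lower with IL-17A and higher with FGF2. A deviation on the IL-17A or FGF2 array alone would move the averages in opposite ways, and so could place a gene in these last 2 groups. The median interaction of the 16 genes was 0.15, above 0 in 10, and the interaction of Tcl1b3 was 1.52. Averaged effects of at least 2-fold numbered 34 higher and 18 lower for IL-17A and 56 and 85 for FGF2, against 1 and 1 for the interaction divided by 2, which carries the same error.

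The enterocyte genes were also read in 2 subsets by site of expression, and the difference between the subsets was not tested. For 9 genes of the small intestine the median averaged effect was −0.90 with IL-17A (−1.31 to −0.66) and −0.42 with FGF2 (−0.65 to −0.18). For 4 of the colon it was −0.23 (−0.83 to −0.06) and −0.89 (−1.11 to −0.75), so the ranges overlapped for IL-17A. The labels give the tissue only as intestine.

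For both factors against untreated, some other lists had these medians, with their percentiles among random lists: NRF2 and redox 0.03 (59.2), Wnt targets 0.00 (55.1), housekeeping 0.19 (90.9), oxidative phosphorylation 0.09 (36.4), tight junction −0.08 (2.8), stem cell 0.21 (97.5), macrophage −0.03 (52.8), tuft −0.25 (13.4), neutrophil 0.22 (92.8, 3 genes) and lymphocyte −0.20 (31.8, 4 genes). Among tight junction genes, Cldn2 was 2.42-fold lower, and among macrophage markers Cd14 was 3.57-fold higher.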
